A study of Mus musculus with 4 samples.

How the data were processed

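Libraries were made from total RNA of retinas with an Illumina TruSeq RNA kit, per the labels' protocols, after 1 h of acute ocular hypertension and a further 5 days. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, without a role for either build, and the read counter, the annotation and the filters are not given in the sources used here. The authors deposited a single table with 4 columns of estimated counts per gene and 4 columns of FPKM. The unit of the count columns was taken from the values, since 80.3% to 82.4% were whole numbers and the column totals differed. The smallest total of a table entry over the 4 libraries was 76.9 reads, so genes with few reads were left out before deposition. The estimated counts divide reads between similar genes, so members of gene families such as crystallins, histones and MHC genes are less certain, and whether reads were assigned by strand is not given in the sources used here. In 15 entries the counts were identical to those of another entry, 22 gene names had been turned into dates, and 4 entries shared a name.

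Column names gave the group by the words WT with ctrl, or case, and a number, different in each column, that no label repeats. The case columns were taken as transgenic because the series has only 2 groups. Since no column could be matched to a single sample, only the count columns were used, and the 4 columns of FPKM were not used. The gene filter and the limma fits were at first taken from those columns, which were dropped after results had been seen, because a group may have no more columns than samples. FPKM was instead worked out from the counts, the column totals and the longest transcript of each name in GENCODE M21, and 167 entries without a match were given the median length of 3472 bases. Longest transcripts overstate the length of many genes and so lower their FPKM. The libraries are separate columns of 2 per group, and the labels do not say how many animals each came from. The Y-linked reads show that TP-1036 and TP-1040 were not from the same animal, and for the others this is not given in the sources used here, so p-values measure the spread between these libraries. The chi-square of the counts was 12.2 times its degrees of freedom between the wild-type libraries and 67.7 times between the transgenic-labelled ones, so neither pair differed by sampling noise alone. The labels give an embryonic age, which is at odds with an injury followed by 5 days, and age was not used. Totals were 28866589 (P1041), 32456452 (P1033), 38508987 (TP-1036) and 41215649 (TP-1040) estimated reads. No sequencing batch or date is given in the labels.

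The design fixed before the data were examined named limma on log2(FPKM + 1), and edgeR only if the table held whole counts instead. The table held FPKM beside counts that were not all whole, so the design's condition for edgeR was not strictly met. After the table had been seen, edgeR on the estimated counts, rounded to whole numbers, became the main test and limma an alternative. Genes with a mean FPKM of at least 1 over the 4 libraries were kept (12687 of 14572). edgeR 4.0.16 with limma 3.58.1 in R 4.3.3 was used with TMM scaling, quasi-likelihood fits and a two-sided test at a Benjamini-Hochberg adjusted p of 0.05. Standard errors are the log2 difference divided by the root of the F statistic, and CPM values use the TMM-scaled library sizes. The common biological coefficient of variation was 13.4%, with 2 residual and 4.39 prior degrees of freedom per gene. The median log2 difference over all tested genes was 0.0023.

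Before the data were examined 44 gene lists were fixed, of retinal cell types, other tissues of the eye and injury processes, and 41 had at least 5 tested members. Each was tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the 41 lists. Within a list, gene p-values were also adjusted over the list alone. The text names Plscr1, then the 12 genes with the largest difference in each direction that lie apart without overlap at an unadjusted p of 0.05, since none passed the adjusted threshold, and draws from each list on up to 6 members past the threshold or else 3 with the largest difference and 3 with the highest mean FPKM, and the sex genes. Genes with clone or model names were skipped, and some genes that the rule takes are not reported here. Names outside that rule were chosen after their values were seen, which are Oasl2, H2-K1, H2-T23, Tap1, Tap2, C1qc, Tgfbr2, Stra6, Ezr, Col6a1, Pmel, Tyrp1, Dct, Mlana and Tyr.

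On data simulated from these libraries' means and sizes with 200 of 12687 genes changed, edgeR called 90 of 100 genes changed 2-fold, 98 of 100 changed 4-fold and 4 of 12487 unchanged genes. DESeq2 1.42.0 called 89, 97 and 10. The simulated genes varied independently, with a spread set by expression level alone and no outlying library. These rates therefore do not give the share of real changes that the tests would find here. In a simulated list test the shifted list passed and 0 of the others did, but simulated members were not correlated. Real lists had estimated correlations up to 0.976 (ribosomal proteins). The simulation thus cannot show how often the preset correlation calls a list wrongly here. Alternatives covered the pseudocount (1 or 0.1), the FPKM minimum (1, 5 or none), median centring, quantile normalization, rescaling to TPM, limma without trend and leaving out each library, and, added after the data were seen, DESeq2, DESeq2 size factors in edgeR and robust dispersion. Biotype, transcript length and GC content came from GENCODE M21, in which 98.9% of names were found. Its build differs from those in the notes, so no coordinates are given. Figures were drawn with matplotlib in Python.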

Results

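RNA was sequenced from whole mouse retinas 5 days after 1 h of acute ocular hypertension, a raised-pressure injury used as a model of glaucoma damage. PLSCR1 is a phospholipid scramblase, a membrane protein that moves phospholipids between the leaflets of the plasma membrane. The series holds 2 libraries from wild-type retinas (P1041 and P1033) and 2 from retinas labelled PLSCR1 transgenic, all on a C57BL/6 background and all from injured eyes. No label ties the columns TP-1036 and TP-1040 to the transgenic group, and they were assigned to it because they are marked case. Uninjured retinas were not analysed here, so each difference below is between genotypes after injury. The table held 14572 entries, and 12687 genes with a mean FPKM of at least 1 were tested.

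Plscr1, the gene named by the transgene, differed by less than the spread between libraries. Its reads numbered 229 and 276 in wild type and 371 and 329 in the transgenic-labelled libraries, or 8.17 ± 0.267 against 8.93 ± 1.22 CPM (reads scaled to library size; SD, n = 2 per group). The difference was 0.13 ± 0.17 on the log2 scale (SE), with an adjusted p of 0.742 (edgeR quasi-likelihood test, Benjamini-Hochberg), and its sign turned to -0.016 without library TP-1036. The labels do not say whether the transgene is of mouse sequence or would be counted in the mouse gene, so these reads neither show nor exclude the transgene, and the libraries are called transgenic-labelled throughout. Of its family, Plscr2 had 2.43 ± 0.0737 against 1.65 ± 0.754 CPM (SD, n = 2). In the list of 14 scramblase and flippase genes 9 had lower and 5 higher values, with the scramblase Xkr4 at -0.68 ± 0.31 (log2, SE). The list as a whole did not pass its test (median -0.21, camera adjusted p = 0.111), and 0 of its members passed when adjusted over the list alone, while 2 fell without P1041 and 7 without TP-1040. The list passed camera without P1041 (adjusted p = 0.00988) and without TP-1040 (adjusted p = 0.00760), and its median was -0.014 without TP-1036.

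The first question of the design was which genes differ between the genotypes after the injury. Apart from crystallins, taken up below, the genes with the largest higher values included several of myeloid cells and of antigen presentation. No test of their grouping was made on the ranked genes. Lyz2, the lysozyme of macrophages and neutrophils, stood at 49.8 ± 1.54 CPM against 8.54 ± 2.02 in wild type (SD, n = 2), a 5.81-fold difference. Serpine3, a serpin family gene, stood at 8.28 ± 0.662 against 1.21 ± 0.224 CPM, and the serine protease gene Prss56 at 16.7 ± 4.09 against 6.10 ± 0.978 CPM. Cd74, the invariant chain of MHC class II, was 8.30-fold higher, and the class II genes H2-Eb1, H2-Aa and H2-Ab1 were 9.46-fold, 7.18-fold and 5.23-fold higher. The sizes depended on single libraries. Log2 differences ran from 2.49 (without TP-1036) to 4.34 (without P1033) for H2-Eb1, and from 2.34 to 3.51 for H2-Aa under the same settings. They ran from 1.84 (without TP-1036) to 2.79 (without TP-1040) for H2-Ab1, and from 2.59 (without TP-1036) to 3.63 (without P1033) for Cd74. Over all alternatives of the processing the lowest values were 1.79 for H2-Eb1, 1.30 for H2-Aa, 1.64 for H2-Ab1 and 2.47 for Cd74. Among the genes with the largest lower values were Slc5a7, the choline transporter of cholinergic neurons, at -1.06 ± 0.23, Grin2a, an NMDA receptor subunit, at -1.02 ± 0.32, Crhr1, a receptor of corticotropin-releasing hormone, at -0.92 ± 0.26, and the transcription factor Isl2 at -0.92 ± 0.33 (log2, SE). Other genes at the lower end were AA386476 at -1.25 ± 0.36, Col25a1 at -1.07 ± 0.31, Trank1 at -1.01 ± 0.34, Coro6 at -0.93 ± 0.25, Snhg11 at -0.91 ± 0.22 and Csmd3 at -0.90 ± 0.34 (log2, SE). Much of the size of several came from library TP-1036, where Col25a1, Trank1, Csmd3 and Grin2a lay at -1.61, -1.68, -1.57 and -1.53 against -0.66, -0.55, -0.45 and -0.61 in TP-1040. In TP-1036 coding genes with longer transcripts also had lower values (Spearman correlation -0.540).

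None of these single-gene differences passed the test over all genes. With edgeR's quasi-likelihood test, 0 of 12687 genes reached a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted values were 0.0620 for Lyz2 and 0.0964 for Serpine3. At an unadjusted p of 0.05 the same test gave 1126 genes, 599 higher and 527 lower. DESeq2 called 55 genes higher and 14 lower. Limma on log2(FPKM + 1), the test that the design named first, called Lyz2 and Serpine3, both higher. The edgeR count was 29 without P1041, 91 without P1033, 27 without TP-1036 and 3923 without TP-1040, so it depended on each single library. By size alone, 24 genes lay at least 2-fold apart on log2(FPKM + 1) without overlap between the groups, against 4 and 10 for the other splits of the 4 libraries into pairs. That number was 50 without P1033 and 138 without TP-1040. Groups did not overlap in 47.8% of the tested genes, where chance gives 33.3% and the other splits gave 34.5% and 17.7%. Barring ties, each gene lies apart in a single split, so these shares make up the whole by construction. Genes also vary together, so no excess over 33.3% can be judged from them. With 2 against 2 libraries an exact two-sided permutation p cannot fall below 0.333.

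**Figure D1:**
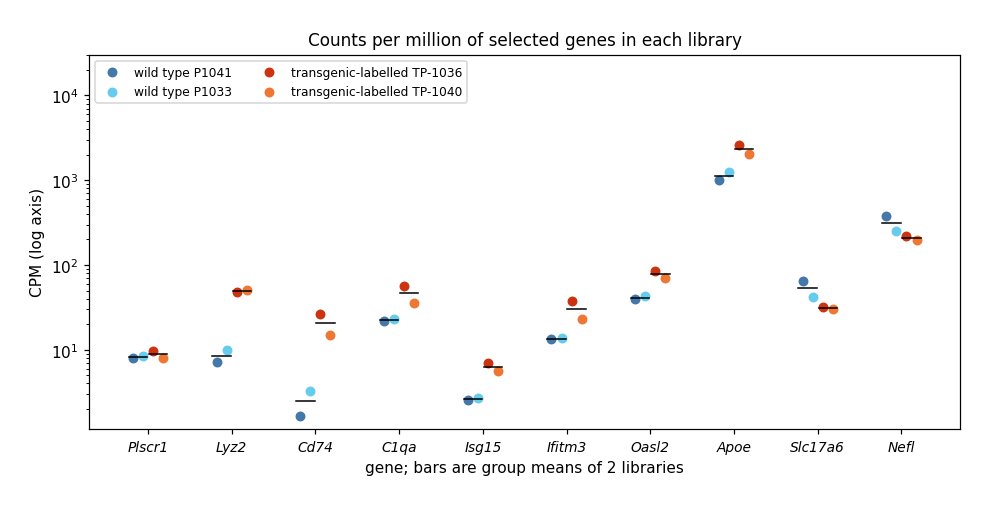
CPM (log axis) of 10 genes in the 4 libraries, with each point a library and each bar the mean of 2 libraries. Plscr1 points overlap, Lyz2 lies at 48.7 and 50.8 in the transgenic-labelled libraries against 7.11 and 9.97 in wild type, and Nefl lies lower at 222 and 195 against 374 and 249.

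Microglia and macrophage markers were higher together. All 25 tested members had a higher value, with a median of 1.03 on the log2 scale (1.30 in library TP-1036 and 0.69 in TP-1040), while the wild-type libraries differed from each other by 0.09. When adjusted over the list alone 20 of the 25 rose, against 0 over all genes, and DESeq2 called 14. Besides Lyz2 and Cd74, these included Gpnmb, a glycoprotein gene of activated phagocytes, at 48.3 ± 0.723 against 18.3 ± 6.28 CPM, C1qa, the first subunit of complement C1q, at 46.2 ± 14.9 against 22.4 ± 0.756 CPM, and Ctss, the lysosomal protease cathepsin S, at 58.1 ± 16.9 against 28.4 ± 2.12 CPM (SD, n = 2). The list passed camera with a preset correlation (adjusted p = 7.37e-44), but not with an estimated correlation (adjusted p = 0.455). Lymphocyte and neutrophil markers had 0 members in the table.

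Interferon-stimulated genes were also higher, and to a similar degree in both transgenic-labelled libraries. All 28 tested members had a higher value in each of them, with a median of 0.77 (0.82 in TP-1036 and 0.59 in TP-1040, against 0.07 between the wild-type libraries). When adjusted over the list alone 22 of the 28 rose, against 0 over all genes, and DESeq2 called 7. Isg15, a ubiquitin-like modifier, stood at 6.30 ± 0.906 against 2.61 ± 0.0855 CPM, and Oas1a, an enzyme of the antiviral RNase L pathway, at 3.43 ± 0.198 against 1.42 ± 0.134 CPM (SD, n = 2). Ifit3, Oasl2 and the membrane protein gene Ifitm3 differed by 0.95 ± 0.14, 0.93 ± 0.13 and 1.17 ± 0.23 (log2, SE). Camera gave an adjusted p of 2.93e-36 with the preset correlation, and the adjusted p = 0.455 with an estimated correlation.

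Antigen presentation, complement and phagocytosis genes followed the same direction. All 17 antigen presentation genes had higher values (median 0.57, 0.88 in TP-1036 and 0.28 in TP-1040), and 8 rose when adjusted over the list alone (5, 11, 5 and 15 without P1041, P1033, TP-1036 and TP-1040 in turn). The 8 were the class II pathway genes H2-Eb1, Cd74, H2-Aa and H2-Ab1 and, with smaller differences, the class I presentation genes H2-T23, Tap1, Tap2 and B2m, the last at 0.69 ± 0.21, whereas H2-K1 at 0.56 ± 0.20 did not pass (log2, SE). Of 13 complement genes 12 had higher values (median 0.72, from 0.38 without TP-1036 to 1.08 without P1033) and 5 rose within the list (9 without P1033 and 11 without TP-1040), with a list median of 1.05 in TP-1036 and 0.40 in TP-1040. The 5 were the C1q subunits C1qa, C1qb and C1qc, C3ar1, the receptor of the C3a fragment, at 10.4 ± 0.923 against 3.92 ± 0.0699 CPM, and C3 itself at 20.9 ± 7.70 against 9.35 ± 3.02 CPM (SD, n = 2). Of 22 efferocytosis and phagocytic receptor genes 19 had higher values (median 0.40) and 9 rose within the list, with the scavenger receptor Stab1 at 1.22 ± 0.16 and the lipid receptor Trem2 at 1.18 ± 0.25. Mfge8, which bridges exposed phosphatidylserine to phagocytes, differed by 0.43 ± 0.17 and did not pass. The 3 lists passed camera with the preset correlation (adjusted p = 1.42e-18, 8.17e-12 and 1.25e-12), and each had an adjusted p = 0.455 with an estimated correlation. These lists share members, such as 5 between the microglia and efferocytosis lists, so they are not independent of each other.

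Glial genes differed less, and mostly in library TP-1036. All 22 Müller glia markers had higher values (median 0.40, 0.59 in TP-1036 and 0.18 in TP-1040), and only Apoe, the lipid carrier, rose when adjusted over the list alone, at 2333 ± 406 against 1133 ± 164 CPM (SD, n = 2). The members that rose numbered 0 without P1041, 2 without P1033, 2 without TP-1036 and 21 without TP-1040. The transcription factor Sox9 differed by 0.63 ± 0.16 and glutamine synthetase (Glul) by 0.23 ± 0.14, and the sign of Glul turned under quantile normalization. Reactive gliosis genes had a median of 0.30 over 26 members, with 0.62 in TP-1036 and 0.10 in TP-1040. The wild-type libraries differed nearly as much, with P1033 above P1041 by a list median of 0.23. In edgeR 0 gliosis genes passed within the list. Without P1033 6 rose, without TP-1040 19 rose, and without TP-1036 1 rose and 3 fell. Gfap, the intermediate filament of reactive glia, stood at 158 ± 34.0 against 106 ± 13.9 CPM and Vim at 297 ± 89.4 against 212 ± 5.12 CPM (SD, n = 2). Camera gave adjusted p values of 1.31e-12 and 3.74e-06 for the Müller glia and gliosis lists with the preset correlation, and an adjusted p = 0.455 and 0.493 with an estimated correlation. Without TP-1036 the gliosis list no longer passed (adjusted p = 0.749, in a range from 3.30e-11 over its alternatives).

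Markers of retinal ganglion cells, the output neurons lost in glaucoma, had lower values. Of 27 members 24 were lower, with a median of -0.37 (-0.25 in TP-1036 and -0.47 in TP-1040, and from -0.15 without P1041 to -0.58 without P1033), and 0 fell in edgeR when adjusted over the list alone, while DESeq2 called Scn1a and Slc17a6. Within the list 0, 16, 12 and 7 fell without P1041, P1033, TP-1036 and TP-1040, and 1 rose in each of the last 3. The glutamate transporter Slc17a6 stood at 30.8 ± 1.15 against 53.7 ± 16.4 CPM, the sodium channel Scn1a at 39.7 ± 11.3 against 75.3 ± 13.8 CPM, the neurofilament Nefl at 208 ± 19.0 against 312 ± 88.4 CPM and Thy1 at 80.3 ± 10.1 against 103 ± 24.6 CPM (SD, n = 2). The transcription factor Pou4f3 had 75 and 75 reads against 116 and 70. The wild-type libraries differed by as much among themselves, since P1033 lay below P1041 with a list median of -0.40. Camera with the preset correlation gave an adjusted p of 1.03e-06 for this list, and the adjusted p = 0.455 with an estimated correlation. The call ended without P1041 (adjusted p = 0.0606) and without TP-1040 (adjusted p = 0.0567), in a range from 9.57e-13 to 0.0606 over its alternatives.

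Amacrine cell and synaptic genes had smaller differences of the same sign, near in size to those between the wild-type libraries. P1033 lay below P1041 with a list median of -0.11 for amacrine and -0.08 for synaptic genes. Amacrine cell markers had a median of -0.14 over 29 members, 22 of them lower and 7 higher. Chat, the acetylcholine-synthesizing enzyme, lay at -0.75 ± 0.21 and Calb2 at -0.58 ± 0.20 (log2, SE). Synaptic genes had a median of -0.10 over 30 members, 18 of them lower and 12 higher. The synaptic median was -0.12 in TP-1036 and -0.03 in TP-1040, and it was -0.031 without TP-1036 and -0.060 without P1041. The active zone gene Rims1 lay at -0.78 ± 0.19 and the glutamate receptor subunit Gria2 at -0.60 ± 0.16 (log2, SE). In both lists 0 members passed within the list in edgeR, while DESeq2 called Rims1. Of synaptic genes 3 fell without P1033, 3 without TP-1036 and 8 without TP-1040, where 1 rose. Of amacrine genes 1 fell without P1033, 1 rose without TP-1036, and 3 fell and 2 rose without TP-1040. The camera calls (adjusted p = 0.0155 and 0.0170) gave adjusted p = 0.467 and 0.498 with an estimated correlation and ended without P1041 and without TP-1040, and for amacrine cells also at a mean FPKM of at least 5. Horizontal cell markers went the other way, with a median of 0.14 over 14 members, and Lhx1 (0.75 ± 0.14, log2, SE) rose within the list, with 0 rising without P1041 or P1033, 1 without TP-1036 and 5 without TP-1040, where 1 fell. Their camera call (adjusted p = 0.0236) gave an adjusted p = 0.455 with an estimated correlation and held in 7 of 14 alternatives. Rod markers had a median of 0.15 over 30 members (0.23 without P1041), 26 of them higher, with a camera adjusted p of 0.000582 and an adjusted p = 0.467 with an estimated correlation, and the call ended without P1033 (adjusted p = 0.115) and under quantile normalization, where the sign of the median turned. Cone markers had a median of 0.11 over 19 members (0.024 without TP-1036 and 0.042 without P1033), with the opsin Opn1sw at 0.21 ± 0.11, and bipolar markers 0.08 over 24 members, and neither list passed (camera adjusted p = 0.149 and 0.183), but the bipolar list did without TP-1036 (median 0.13, adjusted p = 0.000567).

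**Figure D2:**
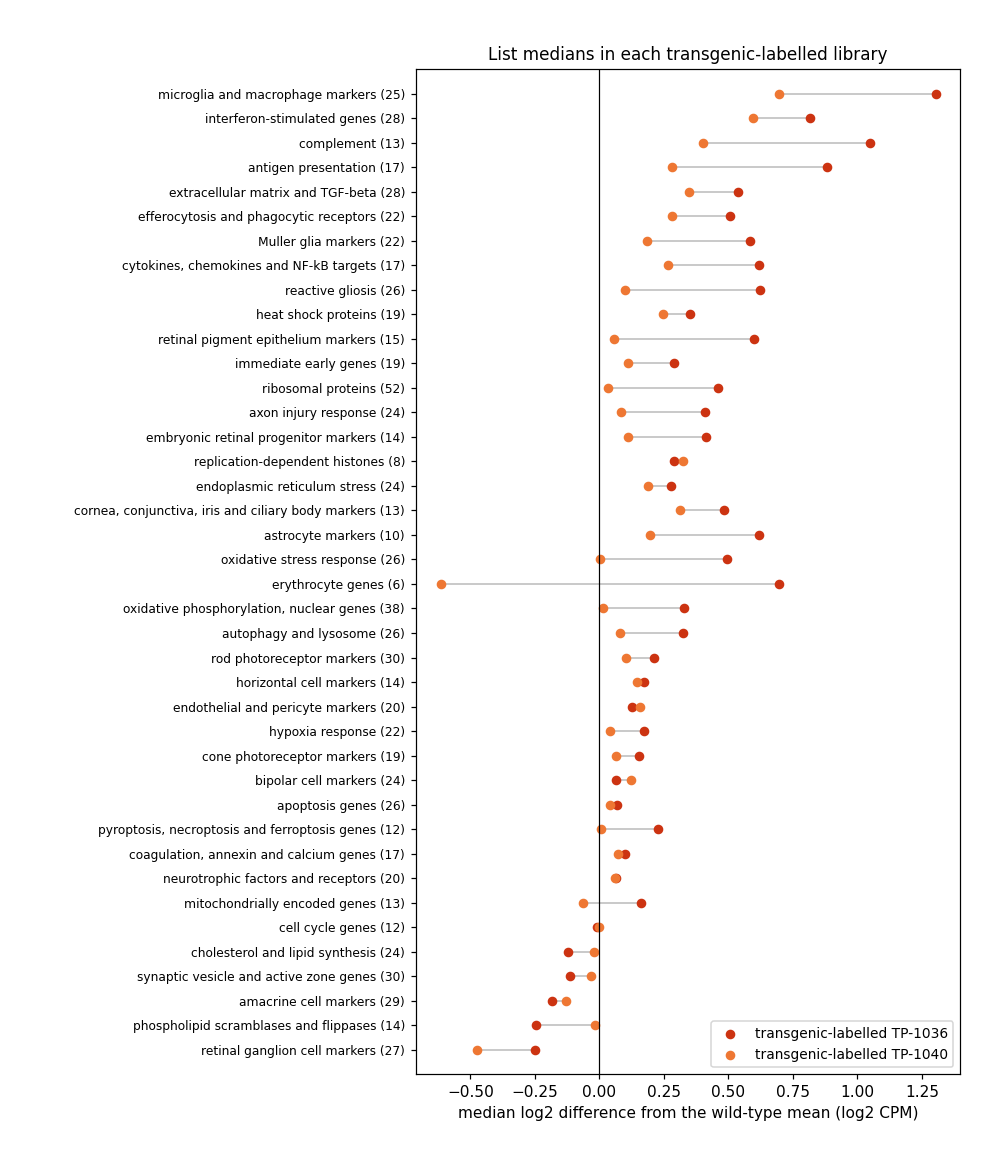
Median log2 difference from the wild-type mean of the members of 40 gene lists in each transgenic-labelled library, with the number of tested members in brackets and the lens list left out for scale. Microglia and macrophage markers (1.30 and 0.69) and interferon-stimulated genes (0.82 and 0.59) lie to the right, and retinal ganglion cell markers (-0.25 and -0.47) to the left.

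Over all 41 lists with at least 5 tested members, camera with a preset correlation of 0.01 passed 29, of which 26 were higher and 3 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.455). The adjustment gave this same value to lists with unlike unadjusted camera p. These were 0.0247 for interferon-stimulated genes, 0.0613 for microglia and macrophage markers and 0.259 for ganglion cell markers. With fry, which tests whether a list's members move one way on balance, 0 passed (smallest adjusted p = 0.0712). The other splits of the 4 libraries into pairs gave 16 and 25 lists with the preset correlation, beside the 29 of the genotypes.

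The transgenic-labelled libraries also differed from each other in reads that the genotype labels do not name. Library TP-1036 held more reads of crystallin genes of the lens list. It had 5574 reads of Cryaa against 52 and 2 in wild type and 122 in TP-1040, and 2391 reads of Crybb2 against 19, 0 and 68. Crybb3 had 860 reads in TP-1036 against 24, 25 and 43, and Cryab, which is also a heat shock protein, 3607 against 1094, 1201 and 1918. The count of 0 for Crybb2 in P1033 allows up to 0.0909 CPM, from counting error only. The lens list had a median of 4.74 in TP-1036 and 0.38 in TP-1040 over 5 members, 4 of them higher and 1 lower. Its camera adjusted p of 0.00158 became an adjusted p = 0.455 with an estimated correlation. The other genes of the list were not in the table, and the tissue that the crystallin reads came from was not tested. On the first principal component, with 66.4% of the variance, TP-1036 lay at 34.6 and the others between -17.8 and -3.02. Library TP-1040 had 1, 0 and 0 reads of the Y-linked genes Ddx3y, Uty and Eif2s3y, against 2584, 1020 and 1284 in P1041, 1666, 736 and 961 in P1033, and 2789, 873 and 1101 in TP-1036. The counts of 0 allow up to 0.0735 CPM in TP-1040. The Y-linked gene Kdm5d had 257 reads there against 1513, 1349 and 991, and the source of those reads was not tested. Of 15 pigment epithelium genes 10 had higher and 5 lower values, with the retinol isomerase Rpe65 at 1.17 ± 0.26, the thyroxine carrier Ttr at 1.42 ± 0.23 and Rgr at 1.06 ± 0.22 (log2, SE), and these, Stra6 and Ezr rose when adjusted over the list alone. Without P1041 2 rose and 2 fell, and without TP-1040 9 rose and 1 fell. Their list had a median of 0.60 in TP-1036 and 0.06 in TP-1040, a camera adjusted p of 7.77e-05 that became 0.0859 without P1041, and an adjusted p = 0.455 with an estimated correlation.

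**Figure D3:**
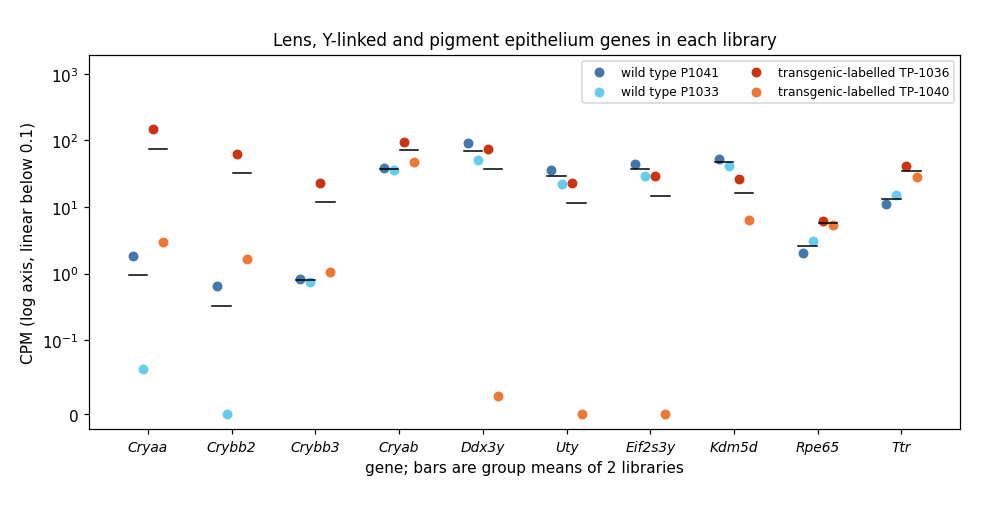
CPM (log axis, linear below 0.1) of lens, Y-linked and pigment epithelium genes in the 4 libraries, with each point a library and each bar the mean of 2 libraries. Cryaa reaches 147 in library TP-1036, and Uty and Eif2s3y lie at 0 in library TP-1040.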

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

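DESeq2, DESeq2 size factors and robust dispersion were chosen after the data were seen, as was edgeR as the main test with limma beside it. Limma on log2(FPKM + 1) had been the test that the design named first, with edgeR only for whole counts in place of FPKM. No paired analysis was possible because the columns carry no replicate numbers. Leaving out a library sets a lone library against a pair, which assumes that it varies as the pair does.

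The count of genes past the adjusted threshold, 0 in edgeR, was 2 (all higher) with limma on log2(FPKM + 1), with a pseudocount of 0.1, after median centring, with quantile normalization and without trend, 1 (higher) without a filter and with robust dispersion, and 69 with DESeq2 (55 higher and 14 lower). Leaving out each library gave 27 to 3923 genes, 19 to 1723 higher and 6 to 2200 lower, with the top of each range without TP-1040, which left TP-1036 alone against wild type. Other alternatives gave 0. Genes at least 2-fold apart without overlap numbered 24, 77 with a pseudocount of 0.1, which widens low values by construction, 37 after rescaling to TPM, 16 to 138 with each library left out, and 17 to 26 otherwise. The 29 lists past camera's threshold became 0 with an estimated correlation and 0 with fry, and were 24 to 31 in the other alternatives.

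The Plscr1 difference of 0.13 ranged from -0.016 (without TP-1036) to 0.27 (without TP-1040), below the threshold in all 14 alternatives, and at a mean FPKM of 5 the gene was not tested. Glul turned to -0.14 and the rod markers' median to -0.029 under quantile normalization. Ddx3y, from -11.28 without TP-1036, turned to 0.074 without TP-1040, the library with 1 read. The median of oxidative stress genes (0.21) turned to -0.033 without TP-1036 and reached 0.49 without TP-1040. Otherwise the causes were not tested. Of the 29 lists called, 13 passed in the same direction in every refit in which they had enough members (the lens list had too few at a mean FPKM of 5) and 16 lost their call in at least 1. Of the 80 other named genes that were put through the alternatives, 31 passed with DESeq2. Pmel, Tyrp1, Dct, Mlana and Tyr were not among the 80. Depth limits low genes such as H2-Eb1, with 10 and 37 reads in the wild-type libraries.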

Other observations

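The tests of sex, of pigmented tissue, of GC and length on ganglion cell markers and of single animals were chosen after the results were seen. For genes of the annotation class TEC in library TP-1036, the predictions were written before their tests were run. The TEC pattern itself was not part of the design fixed before the data were examined.

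Matrix and stress-response genes formed further groups with higher values in both transgenic-labelled libraries. Extracellular matrix and TGF-beta genes had a median log2 difference of 0.48 over 28 members (0.54 in TP-1036 and 0.35 in TP-1040, and 0.25 without P1041), and when adjusted over the list alone 3 rose and 1 fell (0, 11, 5 and 14 rose without P1041, P1033, TP-1036 and TP-1040 in turn). The 4 were the receptor Tgfbr2, Tgfb1 and Timp2, and the collagen gene Col6a1. The ligand Tgfb1 differed by 1.08 ± 0.26, the metalloproteinase inhibitor Timp2 by 0.50 ± 0.12, and Col6a1 by -0.65 ± 0.12 (log2, SE). Heat shock genes had a median of 0.30 over 19 members, with Hspb1 at 7.84 ± 0.160 against 3.96 ± 0.662 CPM (SD, n = 2), and Hspb1 and Hspa1b (0.67 ± 0.13) rose within the list, where the count was 1 without P1041 and 12 without TP-1040. Endoplasmic reticulum stress genes had a median of 0.26 over 24 members, with the chaperone Hspa5 at 0.57 ± 0.17 and Pdia6 at 0.50 ± 0.14, and 0 passed within the list in edgeR, while 1 rose without TP-1036, and 12 rose and 2 fell without TP-1040. Each of these lists passed camera with the preset correlation and had an adjusted p = 0.455 with an estimated correlation.

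Replication-dependent histone genes had a median of 0.27 over 8 members, nearly equal in TP-1036 (0.29) and TP-1040 (0.33), and Hist2h3c2 (0.65 ± 0.14) and Hist1h2bc (0.51 ± 0.13) rose within the list, where 0 did without P1041 and 1 without P1033. The immediate early gene Egr1 differed by 0.74 ± 0.17 and Wfdc1, in the list of anterior eye markers, by 0.83 ± 0.22 (log2, SE), neither passing within its list in edgeR, while DESeq2 called Egr1. The lists of apoptosis, cell cycle and hypoxia genes did not pass camera (adjusted p = 0.340, 0.829 and 0.183), nor with any library left out. Ribosomal protein genes had a median of 0.46 in TP-1036 and 0.04 in TP-1040, and their call ended without TP-1036 (adjusted p = 0.133, in a range from 1.77e-21 over the alternatives), and they had an adjusted p = 0.498 with an estimated correlation.

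The microglia and macrophage markers were higher in both transgenic-labelled libraries. Sex of the animals was argued against as the whole account, since library TP-1036, with Y-linked reads as in wild type, had a list median of 1.30 against the wild-type mean, above the 0.69 of library TP-1040. Carry-over of pigment epithelium and choroid, tissues with their own macrophages, may contribute and remains open. The pigmented-cell genes Pmel, Tyrp1, Dct, Mlana and Tyr had a median of -0.30 in the transgenic-labelled mean, but 0.50 in TP-1036 and -1.21 in TP-1040. The wild-type libraries differed by 0.95 in that median. Rpe65, Ttr and Rgr were higher in both libraries, but the pigment epithelium list had a median of 0.60 in TP-1036 and 0.06 in TP-1040. The genotype, and any difference between single animals, remain open as well.

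Genes of the annotation class TEC were lower in library TP-1036, and besides them only protein-coding genes were examined. There, 329 of 380 genes annotated TEC (transcripts still to be experimentally checked) lay below the mean of the other 3 libraries, with a median of -0.60, against 0.02 for 12140 protein-coding genes. The other libraries were not alike, since the TEC median minus that of coding genes was 0.42 in P1033, 0.17 in P1041, 0.01 in TP-1040 and -0.62 in TP-1036, each against the mean of the other 3. A loss of unspliced RNA confined to TEC genes inside coding genes was argued against. The 138 TEC genes outside any protein-coding gene lay as far below coding genes (-0.60) as the 166 inside them (-0.61). Unspliced reads from neighbouring genes were not measured, so the test cannot decide on unspliced RNA in general. Coding genes of TP-1036 also fell with gene span, introns included (Spearman correlation -0.363, against 0.187 to 0.283 in the others). Removing a smooth trend on GC content left -0.48, and removing 1 on transcript length left -0.74, so neither trend could account for the whole gap. The coding genes of TP-1036 did follow length across genes, from a median of 0.26 in the shortest of 4 length classes to -0.25 in the longest. No biological explanation of the TEC gap was tested, and the cause remains open.

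Ganglion cell markers were lower in both transgenic-labelled libraries. GC content and transcript length were argued against as the whole account, as the list median was -0.45 after both trends were removed. A difference between single animals or libraries may account for the pattern, because the wild-type libraries differed by 0.40 in the list median, against 0.37 between the groups. The genotype cannot be excluded by this, and remains open.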
